A study of Homo sapiens with 495 samples.

How the data were processed

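RNA levels were measured on 1-colour Affymetrix arrays in 56 established human tumour cell lines of the NCI-60 panel, a set of lines from 9 tissues of origin. Cells in RPMI-1640 medium with fetal bovine serum were plated 24 h before treatment and then kept with 0, 200 or 2000 nM gemcitabine for 2, 6 or 24 h, at a final DMSO content of 0.25%. RNA was purified on Qiagen RNeasy columns, checked for quality and labelled with biotin by the Affymetrix one-cycle procedure. Each line had at most 1 array per dose and time, and 495 arrays were used.

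The deposited values, normalized by the authors, are in log2 units as far as their range shows. They ran from 2.52 to 14.1, with array medians of 4.93 to 5.33. The base of the logarithm was inferred from that range, because the labels do not state it, and the normalization method is not given in the sources used here. No further normalization was applied for the main results. The number of arrays, not a count of reads, limits the precision.

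Of 22277 probe sets, 19070 had 1 gene symbol, 1043 had several and 2164 had none. Probe sets with 1 symbol were used, except 31 for sex-linked genes, which were left out. Each of the resulting 11939 genes was represented by its probe set with the highest mean over all arrays, a choice that concerned the 4304 genes with several probe sets. Among 233 named genes and comparisons that were called and had several probe sets, 1 had another probe set called in the opposite direction.

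Dose, time, cell line and tissue were taken from the labels, and arrays were paired by the cell line in their titles. Lines were the replicates and were taken as independent of each other. Whether any lines came from the same donor was not examined. For each dose and time, limma 3.58.1 in R 4.3.3 tested each gene's mean paired difference over lines, with lmFit and eBayes, 2-sided, and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. The same test compared 2000 with 200 nM at each time, and the change in the paired difference between times at each dose. It also compared times on the 0 nM arrays. A moderated F test compared the response at 24 h between the 8 tissues with at least 5 lines, which left out prostate with 2 lines. Tables were handled with the R package data.table (version 1.17.8), and figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

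Gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The 20 lists covered p53 targets, G1/S and DNA replication, G2/M and mitosis, histones, replication stress and DNA repair, gemcitabine transport and metabolism, NF-kB targets and interferon-stimulated genes. They also covered immediate early and AP-1 genes, ATF4 and the unfolded protein response, cholesterol synthesis, apoptosis regulators, ribosome biogenesis, heat shock, hypoxia and glycolysis, and NRF2 targets. The remaining 4 held melanocytic, leukocyte, epithelial, and fibroblast and mesenchymal markers. Members were counted with p adjusted over all genes and adjusted over the list alone. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 20 lists of a comparison, with an estimated correlation and fry, which tests whether a list's genes move on balance one way, as alternatives. List tests in the comparison of 2000 with 200 nM and on the 0 nM arrays, and contrasts of each tissue with the others, were added after the data were seen.

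Genes were named by size of change among those called with the same sign in at least 75% of lines. The numbers taken were 12 each way per dose at 24 h, 10 at 6 h, 5 at 2 h, 8 for the dose comparison and 5 for the time comparisons. For tissues the 10 genes with the smallest p were taken, and from each list up to 4 called members with the largest change. CDKN1A, MDM2, GDF15, FAS, RRM1, RRM2, DCK, CDA, SLC29A1, TYMS, CCNE2 and ATF3 were always followed. RRM2B was to be followed too, but had no probe set with 1 symbol. Members that moved against their list, further members given as examples, and actin and the probe sets without a symbol were chosen after their values were seen.

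The similarity of both doses was the Pearson correlation across genes of their mean changes. It was set against 99 simulations in which the signs of the lines' differences were flipped, because both doses share the 0 nM arrays, and against 50 random splits of the lines into 2 sets that share none. Levels on the 0 nM, 6 h array were related to the 24 h response over lines for 11 predictors and 3 measures of response, 33 relations in all. Pearson's r and Spearman's rho were given with p from 100000 permutations.

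The alternatives fixed in advance were no pairing by line, 1 fit over all arrays, arrays centred on their medians, quantile normalization, the dimmest 25% of genes left out, and the mean of a gene's probe sets. Every probe set on its own, eBayes with trend and robust settings, leukemia lines left out and only lines with all 9 arrays were also among them. Leaving out 3 arrays whose profiles stood apart and a covariate for the actin 3′ minus 5′ probe difference were chosen after seeing the data. So was the relation of that difference to the SD over genes of a line's changes. The design was tested on simulated data: of genes changed by 0.5 on the log2 scale 98.5 to 100% were recovered, and of genes changed by 0.2 between 41.8 and 98.5%. In those simulations 3.31 to 6.77% of calls were false. Genes were drawn there independently of each other with normal noise. These rates thus do not cover correlation between genes on real arrays.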

Results

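RNA levels of 11939 genes were measured in 56 human tumour cell lines of the NCI-60 panel after exposure to gemcitabine, a deoxycytidine analogue that is phosphorylated by the kinase DCK and blocks DNA synthesis. The lines came from lung (9), melanoma (9), kidney (7), breast (6), colon (6), leukemia (6), ovary (6), the central nervous system (CNS, 5) and prostate (2). At 0 nM there were 53, 56 and 56 arrays at 2, 6 and 24 h. At 200 nM there were 56, 54 and 55, and at 2000 nM 55, 54 and 56. All 9 arrays were present for 48 lines, 8 for 7 lines and 7 for 1 line. Array medians lay between 4.93 and 5.33 on the log2 scale, and every one of the 495 arrays correlated best with another array of its own line (lowest r = 0.981 across probe sets, which are not independent replicates). Changes are given as mean log2 differences with the SD over lines, and the number of arrays limits their precision.

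In MCF7, a breast line, the array labelled 0 nM at 24 h had 11.25 for the cell cycle inhibitor CDKN1A and 12.31 for the stress cytokine GDF15, close to the array labelled 200 nM at 24 h with 11.31 and 12.28. The MCF7 array labelled 2000 nM at 24 h had 7.76 and 6.52. In A498, a renal line, the array labelled 2000 nM at 6 h had a level of 7.59 for cyclin E2 (CCNE2), against 8.99 at 0 nM and 9.88 at 200 nM at that time. These 3 arrays were kept as labelled, and counts without them are given where they are discussed.

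**Figure D1:**
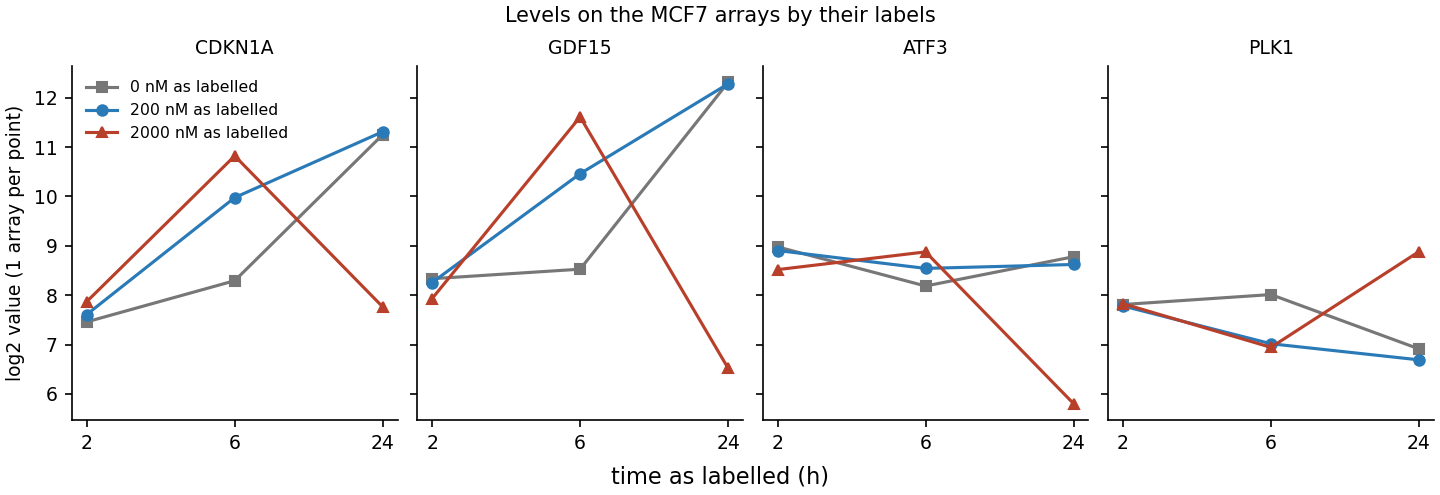
Log2 levels of CDKN1A, GDF15, ATF3 and PLK1 on each MCF7 array, by labelled dose (nM) and time (h), with 1 array per point. At 24 h CDKN1A was at 11.25 on the array labelled 0 nM, 11.31 on that labelled 200 nM and 7.76 on that labelled 2000 nM.

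The question behind the series was how transcriptional responses to anticancer drugs unfold over time across the panel. Against the 0 nM arrays of the same lines, few genes changed at 2 h, the response at 6 h was led by immediate early genes, cyclin E genes and a loss of mitotic transcripts, and by 24 h CDKN1A, ATF3 and CXCL8 were at least 4.25-fold higher. At 200 nM 14 genes changed at 2 h (1 up, 13 down, 53 lines), 1181 at 6 h (737 up, 444 down, 54 lines) and 5422 at 24 h (2734 up, 2688 down, 55 lines). At 2000 nM the counts were 18 (4 up, 14 down, 52 lines), 1805 (1083 up, 722 down, 54 lines) and 5399 (2689 up, 2710 down, 56 lines). Most changes were small: at least 1.5-fold rises and falls numbered 12 and 24 at 6 h and 254 and 82 at 24 h at 200 nM, and 43 and 32, then 292 and 105, at 2000 nM. Without pairing by line the counts at 2, 6 and 24 h were 0, 56 and 1105 at 200 nM and 1, 83 and 1358 at 2000 nM, and in 1 fit over all arrays those at 2 and 6 h were 3 and 454, and 3 and 957. The balance of rises and falls depended on whether arrays were centred. Centring on array medians shifted all genes by -0.065 and -0.0601 at 24 h. It gave 1927 up and 5565 down at 200 nM and 2012 and 5198 at 2000 nM. At 6 h it gave 490 and 1087, and 748 and 2103. Quantile normalization kept the 24 h balance, with 2705 up and 2631 down, and 2664 and 2642 at the respective doses. At 6 h it gave 688 and 507, and 949 and 1003.

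**Figure D2:**
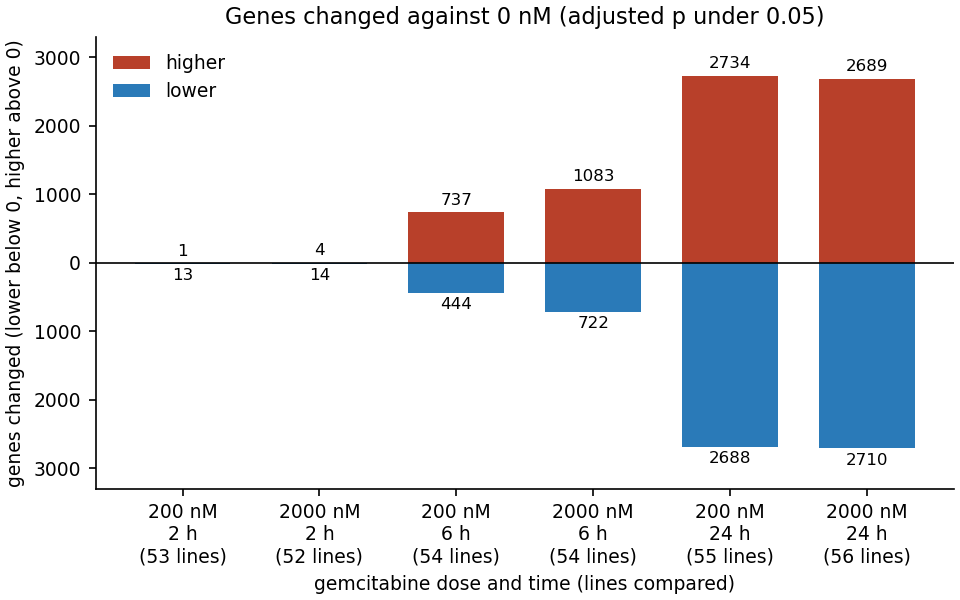
Number of genes higher or lower than at 0 nM (limma, adjusted p under 0.05) at each dose (nM) and time (h). At 24 h 5422 genes changed at 200 nM and 5399 at 2000 nM.

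At 2 h transcripts of the linker histones H1-4 and H1-2 were lower. H1-4 fell by 0.30 (SD 0.44, lower in all but 8 of 53 lines, adjusted p = 0.00499) at 200 nM and by 0.42 (SD 0.47, all but 7 of 52 lines, adjusted p = 2.11e-05) at 2000 nM. H1-2 changed by -0.19 (SD 0.22) and -0.25 (SD 0.24), and the core histone H4C11 by -0.20 (SD 0.32) and -0.24 (SD 0.28). At 200 nM the mitotic kinesin KIF20A was also lower, at -0.10 (SD 0.14), and the chaperone DNAJA1 was higher at 0.07 (SD 0.10), the single rise. The rises at 2000 nM were RSRP1 (0.21, SD 0.23, 44 of 52 lines), DDIT4, an inhibitor of mTOR signalling (0.16, SD 0.28), ZFP36, which promotes mRNA decay (0.14, SD 0.19), and KHDC4 (0.13, SD 0.14). Of 26 measured histone genes, 3 fell at each dose and none rose (6 and 9 fell adjusted over the list alone). The list mean was -0.0578 ± 0.00982 (SE, 53 lines) and -0.079 ± 0.0108 (SE, 52 lines), with camera adjusted p = 3.73e-07 and 1.87e-12. Of the 26 histones 8 are left without the dimmest 25% of genes, and the list was then not called at 200 nM (adjusted p = 0.20).

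The G2/M and mitosis list was already lower at 2 h, with means of -0.0433 and -0.0384 and camera adjusted p = 3.85e-22 and 1.64e-12, although 1 of 36 members at 200 nM and none at 2000 nM fell on their own (16 and 9 adjusted over the list alone). At 200 nM the heat shock list was higher (1 of 12 rose, 4 adjusted over the list alone, adjusted p = 0.000913). At 2000 nM the ATF4 and unfolded protein response list was higher (1 of 20 rose, 4 adjusted over the list alone, adjusted p = 0.000237), and the ribosome biogenesis list was called with adjusted p = 0.00424. These calls held with an estimated correlation, but without pairing by line those for heat shock (adjusted p = 0.37), ATF4 (0.239) and ribosome biogenesis (0.214) were lost. Further lists called at 2000 nM did not hold, with adjusted p with an estimated correlation of 0.108 for p53 targets, 0.0839 for G1/S, 0.164 for AP-1 genes, 0.164 for heat shock and 0.0546 for fibroblast markers. CDKN1A and ATF3, each induced by stress, showed 0.04 and 0.03 at 200 nM and 2 h, and neither passed (adjusted p = 0.985 and 0.99).

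At 6 h immediate early transcription factors rose in most lines. ATF3, a stress-induced factor, rose 3.03-fold (SD 1.72 on the log2 scale, 49 of 54 lines, adjusted p = 9.09e-08) at 200 nM and 5.29-fold (log2 2.40, SD 2.06, 48 of 54 lines, adjusted p = 1.14e-10) at 2000 nM. FOS rose by 1.45 (SD 1.93) and 2.20 (SD 2.22), EGR1 by 1.601 (SD 2.06) and 2.11 (SD 2.27), and JUN by 0.95 (SD 1.52) and 1.37 (SD 1.56). Of 22 measured immediate early and AP-1 genes 14 rose at 200 nM and 20 at 2000 nM, with none lower (17 and 22 adjusted over the list alone), and the list mean was 0.537 ± 0.0949 and 0.885 ± 0.116 (SE, 54 lines). The phosphatase DUSP1 rose by 0.79 (SD 0.98) and 1.33 (SD 1.27).

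Transcripts of mitosis fell in nearly every line by 6 h, while those of G1/S rose. PSRC1, a microtubule-associated protein, fell 2.51-fold (log2 -1.33, SD 0.59, lower in all 54 lines, adjusted p = 1.46e-21) at 200 nM and 2.79-fold (log2 -1.48, SD 0.62) at 2000 nM. The mitotic kinase PLK1 fell by 1.01 (SD 0.52) and 1.17 (SD 0.57), its activator BORA by 0.95 at each dose, and the kinase AURKA by 0.93 (SD 0.41) and 1.03. All 36 measured genes of the G2/M and mitosis list fell at both doses (36 adjusted over the list alone), with a list mean of -0.529 ± 0.0291 and -0.585 ± 0.0302 (SE, 54 lines, 0 of 54 lines higher). CCNE2, which drives entry into S phase, rose 1.86-fold (log2 0.90, SD 0.48, 54 of 54 lines, adjusted p = 2.74e-18) at 200 nM and by 0.94 (SD 0.55, 53 of 54 lines) at 2000 nM. CCNE1 rose by 0.81 (SD 0.40) and 0.88, the licensing factor CDC6 by 0.57 (SD 0.31) and the ubiquitin ligase adaptor DTL by 0.55 (SD 0.24) at 200 nM. Of 35 measured G1/S and DNA replication genes 31 rose and none fell at each dose (32 adjusted over the list alone), with means of 0.24 ± 0.0151 and 0.251 ± 0.0212 (SE). Camera gave adjusted p = 5.84e-140 for G2/M and 1.13e-56 for G1/S at 200 nM, and 4.47e-08 and 5.93e-07 with an estimated correlation.

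CDKN1A, the p53 target that arrests the cell cycle, rose by 0.72 (SD 0.69, 49 of 54 lines, adjusted p = 5.18e-09) and 0.93 (SD 0.79), and PMAIP1, which encodes the pro-apoptotic protein NOXA, by 0.65 (SD 0.65) and 0.93. Of 26 measured p53 targets 16 rose at 200 nM and 18 at 2000 nM (16 up with 1 down, and 18 up, adjusted over the list alone), with means of 0.211 ± 0.0357 and 0.296 ± 0.0458 (SE). GDF15 rose by 0.57 (SD 0.99), FAS, a death receptor, by 0.26 and MDM2, the inhibitor of p53, by 0.22 (adjusted p = 0.00347) at 200 nM. Of 20 measured NF-kB targets 8 rose at 200 nM and 16 at 2000 nM (10 and 17 adjusted over the list alone), among them the chemokine CXCL8 (0.58, SD 0.87, and 1.08, SD 1.30) and the feedback inhibitor TNFAIP3 (0.46 and 0.89). Of 20 ATF4 and unfolded protein response genes 10 and 12 rose (11 and 14 adjusted over the list alone), with DDIT4 at 0.74 (SD 0.82) and 0.89 and DDIT3 at 0.42 and 0.75. The lists for p53 targets, NF-kB targets and ATF4 held with an estimated correlation, with adjusted p = 0.0286, 0.0286 and 0.0256 at 200 nM and 0.0441, 0.00901 and 0.00901 at 2000 nM.

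Smaller list changes at 6 h were seen for histones (6 and 7 of 26 fell), cholesterol synthesis (4 and 5 of 14 rose, with INSIG1, a brake on sterol synthesis, at 0.27 at 200 nM) and apoptosis regulators (4 of 20 rose at each dose, with 1 lower at 2000 nM). Adjusted over the list alone these counts were 6 and 8 histones, 4 and 6 sterol genes, and 5 and 4 apoptosis regulators. These held with an estimated correlation at 200 nM (adjusted p = 0.0281, 0.0286 and 0.0286) but not at 2000 nM (adjusted p = 0.114, 0.0917 and 0.0565 with an estimated correlation). Without pairing by line the cholesterol call was lost at both doses (adjusted p = 0.126 and 0.0796). Of 27 replication stress and DNA repair genes 10 and 11 rose and 2 fell at each dose (16 and 14 rose and 4 and 3 fell adjusted over the list alone), with the nuclease EXO1 at 0.35 (SD 0.25) and 0.46 and the mitotic entry kinase WEE1 at -0.27 (SD 0.24) at 200 nM. That call was lost, with adjusted p = 0.051 and 0.0565 with an estimated correlation, but at 2000 nM it held (adjusted p = 0.0108 with an estimated correlation) without the A498 array that stood apart. Ribosome biogenesis (3 and 5 of 18 fell, 4 and 9 adjusted over the list alone, with 1 higher at 2000 nM) was lost too, with adjusted p = 0.119 and 0.077 with an estimated correlation, as was hypoxia at 200 nM (4 of 20 rose, 4 adjusted over the list alone, adjusted p = 0.051 with an estimated correlation). Among genes of gemcitabine metabolism RRM2, a subunit of ribonucleotide reductase, rose by 0.11 (SD 0.18, 43 of 54 lines) at 200 nM, whereas the transporter SLC29A1 (0.11, adjusted p = 0.0672), TYMS (0.06, 0.0599), RRM1 (0.05, 0.289), DCK (0.05, 0.251) and the deaminase CDA (0.02, 0.867) did not pass.

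**Figure D3:**
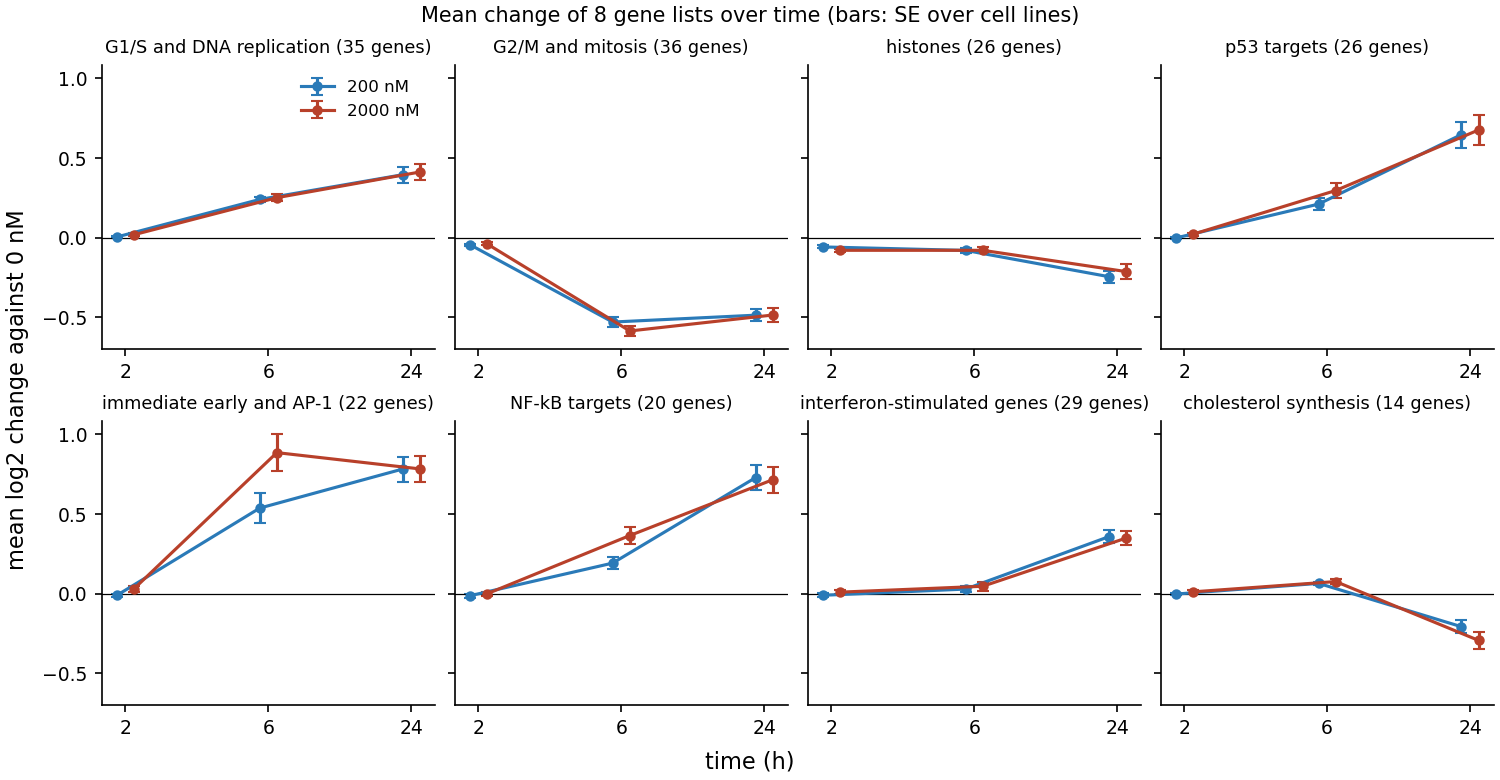
Mean log2 change from 0 nM of 8 gene lists (mean and SE over 52 to 56 lines) at 2, 6 and 24 h, at 200 and 2000 nM. The G2/M and mitosis list was at -0.529 at 6 h and -0.486 at 24 h at 200 nM, while p53 targets went from 0.211 to 0.647.

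By 24 h CDKN1A had risen in every line at 200 nM, 4.25-fold on average (log2 2.09, SD 0.95, 55 of 55 lines, adjusted p = 1.04e-20), and 4.36-fold at 2000 nM (log2 2.12, SD 1.29, 55 of 56 lines, adjusted p = 4.89e-16). ATF3 had risen 7.47-fold (log2 2.90, SD 1.87, 54 of 55 lines) and 7.59-fold (log2 2.92, SD 1.91, 55 of 56 lines). Further p53 targets were GADD45A, a stress sensor (1.89, SD 1.30, and 2.00), GDF15 (1.44, SD 1.499, and 1.34), FAS (1.18, SD 0.97, and 1.19) and MDM2 (0.56, SD 1.00, and 0.67), the last higher in 39 of 55 lines at 200 nM. Of 26 measured p53 targets 21 rose at each dose and 1 fell (21 and 22 rose adjusted over the list alone), and the list mean was 0.647 ± 0.0814 (SE, 55 lines) and 0.676 ± 0.0967 (SE, 56 lines). The member that fell at 200 nM was FBXO22 (-0.12), part of a ubiquitin ligase. Camera gave adjusted p = 7.54e-09 and 2.52e-08, and the calls were lost with an estimated correlation (adjusted p = 0.203 and 0.231). The actin 3′ minus 5′ probe difference, a sign of RNA quality, averaged 1.07 at 0 nM, 1.27 at 200 nM and 1.32 at 2000 nM at 24 h. It was higher than in the paired 0 nM array in 46 of 55 lines and 44 of 56 lines, while at 2 and 6 h its mean change lay between -0.0872 and -0.0146. The same difference between GAPDH probes changed by 0.0396 (SD 0.26, higher in 29 of 55 lines) and 0.028 (SD 0.198, 34 of 56 lines) at 24 h, beside 0.21 (SD 0.461) and 0.252 (SD 0.465) for actin.

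Inflammatory genes were high at 24 h. CXCL8 rose 5.07-fold (log2 2.34, SD 1.86, 52 of 55 lines, adjusted p = 3.33e-12) at 200 nM and 5.22-fold (log2 2.38, SD 1.84) at 2000 nM, TNFAIP3 by 1.72 (SD 1.505) and 1.77, and at 200 nM the signalling adaptor TRAF1 by 1.00 and the cytokine IL6 by 0.99. Of 20 measured NF-kB targets 19 and 18 rose and none fell (19 and 19 adjusted over the list alone), with means of 0.728 ± 0.0802 and 0.715 ± 0.0814 (SE). Among interferon-stimulated genes 23 of 29 rose and 1 fell at each dose (23 and 1 adjusted over the list alone), with IRF1 (0.78, 51 of 55 lines), OAS3 (0.77, 50 of 55 lines) and ISG15 (0.67, SD 0.66, 46 of 55 lines) as examples at 200 nM, where IFIT1 fell by 0.29. Immediate early and AP-1 genes stayed higher than at 0 nM, with 19 and 18 of 22 up and 1 down, MYC at -0.41 at 200 nM (19 and 19 up adjusted over the list alone). The growth factor HBEGF rose by 1.74 (SD 1.06) and 1.73 (SD 1.15), and the AP-1 family member MAFF by 1.58 (SD 1.24) and 1.62 (SD 1.23). With an estimated correlation the adjusted p was 0.09 and 0.138 for NF-kB targets, 0.0932 and 0.149 for interferon-stimulated genes, and 0.09 and 0.136 for AP-1 genes. At 24 h the actin probe difference changed by 0.21 (SD 0.461) at 200 nM and 0.252 (SD 0.465) at 2000 nM. Its relation to single lists was not tested.

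Cell cycle genes remained divided at 24 h. PLK1 fell 3.32-fold (log2 -1.73, SD 0.64, lower in all 55 lines, adjusted p = 2.33e-24) at 200 nM and 3.37-fold (log2 -1.75, SD 0.81) at 2000 nM. KIF20A fell by 1.41 and 1.45, CDC20, an activator of the anaphase-promoting complex, by 1.29 (SD 0.55) and 1.35, and cyclin B1 (CCNB1) by 0.96 and 1.03. In the G2/M list 32 and 30 of 36 fell and 3 rose (32 and 30 fell and 3 rose adjusted over the list alone), with means of -0.486 ± 0.0364 and -0.485 ± 0.0461 (SE). The 3 that rose at 200 nM were the kinase CDK1 (0.21), MELK (0.22) and NUSAP1 (0.18). CCNE2 rose 2.34-fold (log2 1.22, SD 0.49, 54 of 55 lines, adjusted p = 6.94e-23) and by 1.22 at 2000 nM, DTL by 1.25 (SD 0.73) and 1.35, CDC6 by 1.03 and CCNE1 by 0.99 at 200 nM. G1/S genes rose in 27 and 28 of 35 cases, and 1 fell (27 and 28 rose adjusted over the list alone), with means of 0.395 ± 0.0511 and 0.412 ± 0.0521 (SE). The helicase subunit MCM6 was the member that fell at 200 nM (-0.36). Of 26 histones 14 fell at each dose (15 and 14 adjusted over the list alone), such as H2BC9 (-0.96, SD 0.78) and H1-2 (-0.69). With an estimated correlation the adjusted p was 0.09 and 0.146 for G2/M, 0.203 and 0.151 for G1/S and 0.247 and 0.393 for histones, beside the same actin changes of 0.21 and 0.252.

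Genes of DNA repair, nucleotide metabolism and cell death were also measured at 24 h. Of 27 replication stress and repair genes 18 rose at each dose, while 4 and 3 fell (19 rose adjusted over the list alone, adjusted p = 0.203 and 0.158 with an estimated correlation). EXO1 (1.00, SD 0.67), RAD51AP1 (0.67), FANCI (0.65) and BRCA1 (0.54) rose at 200 nM, and the checkpoint genes WEE1 (-0.35), RAD17 (-0.32), CHEK1 (-0.15) and CHEK2 (-0.12) fell. RRM2 rose 1.53-fold (log2 0.62, SD 0.42, 51 of 55 lines) and by 0.54, RRM1 1.4-fold (log2 0.49, SD 0.31, 52 of 55 lines) and by 0.42, DCK by 0.37 (SD 0.47) and 0.42, CDA by 0.28 (SD 0.58, adjusted p = 0.00151) and 0.30, and TYMS by 0.29 and 0.23. The equilibrative transporter SLC29A1 showed 0.00 and 0.02 (adjusted p = 0.972 and 0.863), while SLC29A2 fell by 0.40 and the nucleotidase NT5C by 0.36 at 200 nM. The gemcitabine list had 6 of 20 up and 3 down at each dose (6 and 3 adjusted over the list alone). As a whole it was not called by camera (adjusted p = 0.179 and 0.357), while fry called it at 200 nM (adjusted p = 0.000181). Apoptosis regulators rose in 13 and 12 of 20 cases with none lower (13 and 12 adjusted over the list alone), led by PMAIP1 (1.47, SD 0.89, and 1.51), with the death receptor TNFRSF10B at 0.82 and BCL2A1, which blocks apoptosis, at 0.63 at 200 nM. That call had adjusted p = 0.0512 and 0.136 with an estimated correlation, and 0.0377 at 200 nM without MCF7. The mean changes of the actin probe difference at 24 h were 0.21 and 0.252, and their relation to these lists was not tested.

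Lists for cholesterol synthesis and ribosome biogenesis were lower at 24 h than at 0 nM. On the 0 nM arrays cholesterol synthesis genes themselves rose from 6 to 24 h. INSIG1 fell by 0.76 (SD 0.78, higher in 10 of 55 lines) and 0.90, the desaturase SCD by 1.01 (SD 0.80) at 2000 nM and the sterol enzyme SQLE by 0.43 at 200 nM. Of 14 cholesterol synthesis genes 8 and 9 fell and 1 rose (8 and 9 fell adjusted over the list alone), with means of -0.207 ± 0.0425 and -0.293 ± 0.0522 (SE). SC5D, a late sterol enzyme, was the one that rose at 200 nM (0.14). Ribosome biogenesis genes fell in 13 and 12 of 18 cases with none higher (13 and 12 adjusted over the list alone), such as RRS1 (-0.50) at 200 nM and the nucleolar protein NCL (-0.38) at 2000 nM. In the ATF4 and unfolded protein response list 10 and 9 of 20 rose and 4 and 5 fell (10 and 9 rose adjusted over the list alone). DDIT3 (1.32 and 1.43), PPP1R15A (1.48 and 1.59) and the endoplasmic reticulum co-chaperone DNAJB9 (0.55 and 0.48) rose, while HSPA5 (-0.08 and -0.12), HYOU1 (-0.19 and -0.29), PDIA4 (-0.12 and -0.20) and SEL1L (-0.12 and -0.11) fell at both doses. Heat shock genes fell in 6 and 7 of 12 cases (6 and 7 adjusted over the list alone), among them HSPE1 (-0.39 and -0.50), and HSPA4L (0.52) rose at 200 nM; the list was called at 2000 nM (adjusted p = 0.0092) and not at 200 nM (adjusted p = 0.0585). The ATF4 list was called at 200 nM (adjusted p = 0.0228, and 0.0609 without the dimmest 25% of genes) and not at 2000 nM (adjusted p = 0.0649), and neither difference between doses is shown by these p. With an estimated correlation the adjusted p was 0.414 and 0.368 for cholesterol synthesis, 0.365 and 0.377 for ribosome biogenesis, 0.371 for ATF4 at 200 nM and 0.279 for heat shock at 2000 nM, beside the actin changes of 0.21 and 0.252.

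Besides the heat shock and gemcitabine lists, camera called neither hypoxia nor NRF2 targets nor any marker list at 24 h at 200 nM. Hypoxia and glycolysis had 5 of 20 up and 6 down (adjusted p = 0.513). NRF2 targets had 1 of 13 up and 6 down (0.27). Among the markers, melanocytic genes had 2 of 9 up and 2 down (0.973) and leukocyte genes 4 of 10 up (0.211). Epithelial genes had 2 of 10 up (0.531), and fibroblast and mesenchymal genes 1 of 10 up and 3 down (0.513). Adjusted over the list alone, the counts were 5 up and 6 down, 1 and 6, 2 and 2, 4 up, 1 up, and 1 up. The hypoxia list had a mean of 0.0198 with a median of -0.0688 and a test pointing down, and ADM, a vasodilator peptide in it, rose by 0.85. At 2000 nM the adjusted p was 0.453 for hypoxia, 0.154 for NRF2 targets, and 0.935, 0.382, 0.935 and 0.389 for the markers in the same order.

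The doses were compared directly within lines to see where more drug gave a different response. At 6 h the immediate early genes were further up at 2000 nM, and at 24 h cholesterol synthesis and heat shock genes were further down. At 2 h no gene differed by limma's test (0 genes, 543 at an unadjusted p under 0.05, 55 lines, and 0 in 1 fit over all arrays). At 6 h 679 genes differed (433 higher and 246 lower at 2000 nM, 53 lines), 2 of them by at least 1.5-fold. ATF3 was 1.74-fold higher (log2 0.80, SD 0.94, 43 of 53 lines, adjusted p = 1.96e-05), FOS was higher by 0.76, DUSP1 by 0.54, GADD45B by 0.50, CXCL8 by 0.49 and CDKN1A by 0.19 (adjusted p = 0.0155), while CCNA2 and PLK1 were at -0.15 each. CCNE2 differed by 0.02 and did not pass (adjusted p = 0.877). AP-1 genes were higher in 20 of 22 cases (adjusted p = 0.00785 with an estimated correlation), NF-kB targets in 10 of 20 (0.00785) and ATF4 genes in 8 of 20 (0.0239), and G2/M genes were lower in 11 of 36 with 1 higher, CKS2 (0.0182). Adjusted over the list alone these counts were 20, 13, 11 with 1 lower, and 23 with 1 higher. p53 targets (6 of 26 higher, 9 adjusted over the list alone) and heat shock genes (3 of 12, 3 adjusted over the list alone) were called at adjusted p = 2.04e-06 and 0.0224, and lost at adjusted p = 0.088 and 0.0575 with an estimated correlation.

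At 24 h 429 genes differed between the doses (206 higher and 223 lower at 2000 nM, 55 lines), none by 1.5-fold. The kinase CDK5 was lower, at -0.29 (SD 0.28, lower in 51 of 55 lines, adjusted p = 1.34e-06), the lipoprotein receptor LRP8 at -0.24 (SD 0.38), FASN, the fatty acid synthase, at -0.21 (SD 0.35) and HMGCS1, an early sterol enzyme, at -0.20 (SD 0.28, adjusted p = 0.000635). SLC25A4, the mitochondrial ADP/ATP carrier, was at 0.20 (SD 0.23, 47 of 55 lines) and TUBGCP3, part of the gamma-tubulin complex, at 0.23 (SD 0.31). Cholesterol synthesis genes were lower in 5 of 14 cases (10 adjusted over the list alone), with a mean of -0.089 ± 0.0183 (SE), and heat shock genes in 5 of 12 (7 adjusted over the list alone), with adjusted p = 0.0213 and 0.00268 with an estimated correlation. ATF3 (0.05, adjusted p = 0.836) and CDKN1A (0.01, 0.959) did not pass. Without the 3 arrays that stood apart 628 genes differed at 24 h and 724 at 6 h, with 423 of the 429 called in the same direction. No gene differed at 6 or 24 h without pairing by line (0 genes), and 1 and 23 did in 1 fit over all arrays.

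Mean responses to both doses were alike at 6 and 24 h, and at 2 h no likeness beyond that given by the shared 0 nM arrays was seen, across genes, which are not independent replicates. Pearson's r was 0.548 at 2 h, 0.877 at 6 h and 0.981 at 24 h, against a highest value of 0.662, 0.828 and 0.931 in 99 sign-flipped simulations that share the 0 nM arrays. Between sets of lines with no array in common, r across the doses was 0.049 at 2 h, 0.701 at 6 h and 0.895 at 24 h. Within 200 and 2000 nM it was -0.016 and 0.054 at 2 h, 0.721 and 0.803 at 6 h, and 0.907 and 0.901 at 24 h. At 2 h neither dose repeated itself across genes, so this measure could not show a likeness of the doses there. At 24 h 2426 genes rose and 2281 fell at both doses, at 6 h 560 and 305, and at 2 h 10 fell and 0 rose. Both doses share the 0 nM arrays, so part of this overlap comes with the design.

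Changes in the response between times were tested within lines. From 2 to 6 h ATF3 and CCNE2 gained and PSRC1 and PLK1 lost, and from 6 to 24 h CDKN1A and CXCL8 gained while INSIG1 turned from higher to lower. At 200 nM the response differed for 702 genes between 2 and 6 h (51 lines) and 4193 between 6 and 24 h (53 lines), and at 2000 nM for 906 (50 lines) and 3984 (54 lines). Without pairing these counts were 2, 78, 13 and 53. ATF3 gained 1.51 and CCNE2 0.82 by 6 h at 200 nM, while PSRC1 changed by -1.21 and PLK1 by -0.92. Between 6 and 24 h CXCL8 gained 1.71 and 1.21 at the respective doses, CDKN1A 1.36 (52 of 53 lines) and 1.17 (53 of 54 lines), HBEGF 1.35 (SD 0.98) and 1.08 (SD 1.00), INSIG1 changed by -1.05 and -1.23, and SCD by -0.90 (SD 0.68) and -1.03 (SD 0.79). Of the genes higher at 6 h at 200 nM 542 were also higher at 24 h (169 if independent), and of those lower 288 (100 if independent), with 47 and 55 called in opposite directions.

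Untreated cultures also changed with time. From 2 to 6 h 2666 genes changed (1152 up, 1514 down, 53 lines), and from 6 to 24 h 4277 (2448 up, 1829 down, 56 lines). Without pairing the counts were 11 and 165. Centred arrays gave 1707 up and 1094 down, and 1601 up and 4661 down. Quantile normalized arrays gave 1352 and 1353, and 2227 and 2051. By 6 h ATF3 fell by 0.86, KLF11, a transcription factor, by 0.92 (SD 0.43), and DDIT4 rose by 0.57. Of 36 G2/M genes 31 rose (adjusted p = 0.0565 with an estimated correlation), of 22 AP-1 genes 15 fell (0.0565), and of 12 heat shock genes 8 fell (0.00329). Adjusted over the list alone, 31 G2/M genes rose, and 17 AP-1 and 9 heat shock genes fell. From 6 to 24 h DDIT4 rose by 0.87 and INSIG1 by 0.82, the cold-induced RNA-binding protein CIRBP fell by 0.83 (SD 0.36, lower in all 56 lines), CCNE2 by 0.44 and SLC29A1 by 0.28. Of 14 cholesterol synthesis genes 12 rose (adjusted p = 0.364 with an estimated correlation), 8 of 12 heat shock genes rose (0.214), 14 of 18 ribosome biogenesis genes fell (0.371) and 21 of 35 G1/S genes fell (0.444). Adjusted over the list alone these counts were 12, 10 with 1 lower, 14 and 24. Responses at 6 and 24 h are measured against these moving 0 nM levels. A lower INSIG1 or higher CCNE2 at 24 h need not mean that treated levels moved by as much. The same holds at 6 h for higher ATF3 and AP-1 genes and for lower G2/M genes.

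The response at 24 h was then compared between tissues of origin. In colon lines IGFBP6, a binder of insulin-like growth factors, rose by 1.72 (SD 0.39, 6 of 6 lines) at 200 nM, with limma adjusted p = 6.29e-08 over 8 tissues, and by 1.92 (SD 0.339) at 2000 nM. The water and glycerol channel AQP3 was higher in colon lines by 2.17 (SD 0.615) and 2.42, and at 2000 nM the intestinal keratin KRT20 by 1.56 and the kinase PTK6 by 1.07. At 0 nM KRT20 had a mean level of 4.98 (SD 2.59) in colon lines. In the other tissues it lay between 3.48 and 3.63, below the lowest array median of 4.93. TRAF1 was higher in renal lines by 3.21 (SD 1.57, 7 of 7 lines) and 3.14 (SD 1.88), against 1.49 in CNS and 1.19 in lung lines at 200 nM. ID1, an inhibitor of differentiation factors, showed 1.21 in leukemia lines against -1.4 in CNS and -1.18 in renal lines at 200 nM. In all, 1814 genes differed between tissues at 200 nM (53 lines) and 1990 at 2000 nM (54 lines), with 1260 called at both doses, which share the 0 nM arrays. Single tissues were set against the others, and 1094 and 759 genes differed for CNS lines, 812 and 885 for colon, 547 and 635 for renal, 255 and 518 for leukemia and 78 and 82 for melanoma. No gene passed for breast, lung or ovarian lines by limma, with 803, 757 and 456 genes at an unadjusted p under 0.05 at 200 nM and 1374, 607 and 387 at 2000 nM. The breast lines include MCF7. Without its arrays that stood apart 1709 and 1863 genes differed between tissues, and no gene passed for breast, lung or ovarian lines, with 659, 740 and 443 at an unadjusted p under 0.05 at 200 nM and 589, 662 and 417 at 2000 nM.

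The lines differed widely in the change of p53 target transcripts at 24 h. Whether p53 itself was active in a line was not tested. At 200 nM the mean change of the 26 p53 targets had a median of 0.407 and an SD of 0.604 over lines, from -0.0255 in NCI-H522 to 2.17 in A549 and 2.79 in NCI-H460, all lung lines, with MCF7 left aside. The MCF7 value of -0.0457 rests on the array labelled 0 nM at 24 h, whose mean p53 target level of 9.003 was close to that at 200 nM (8.96), while the 0 nM, 6 h array had 7.42. At 2000 nM MOLT-4, a leukemia line, and NCI-H460 had 2.5 each, and MCF7 had -1.88 from the arrays labelled 0 nM and 2000 nM that stood apart. NF-kB targets rose most in the renal line CAKI-1 (3.04) at 200 nM.

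**Figure D4:**
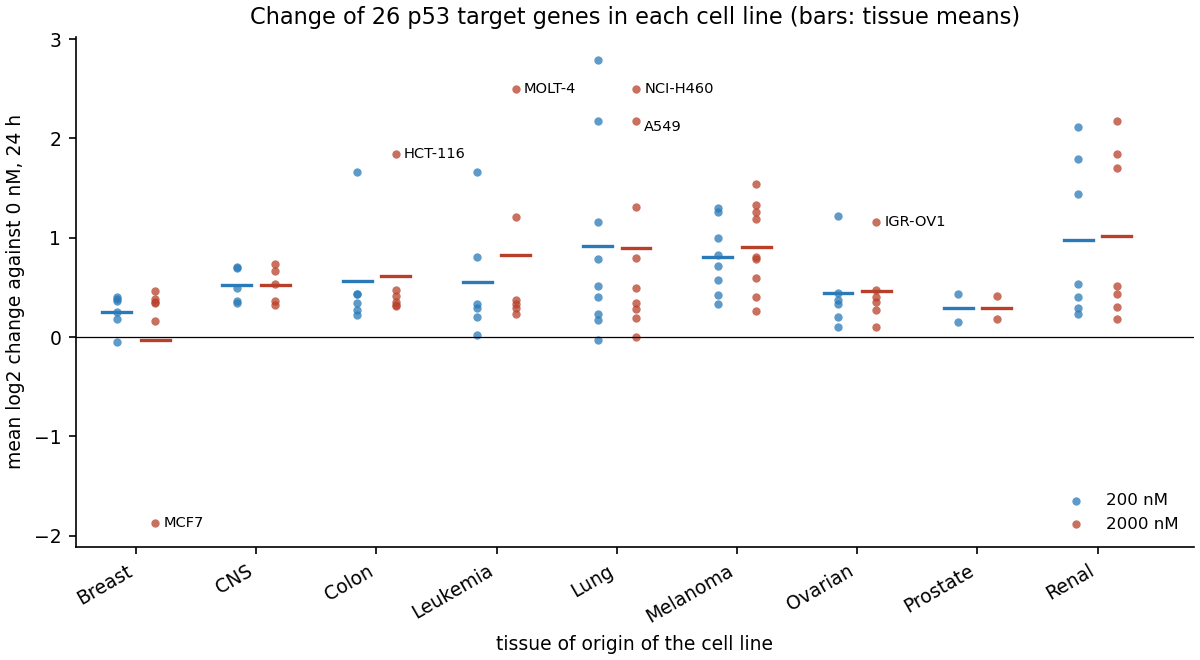
Mean log2 change from 0 nM of 26 p53 targets at 24 h in each line, by tissue, at 200 and 2000 nM, with 1 point per line and bars at tissue means. NCI-H460 was at 2.79 at 200 nM, and MCF7 at -1.88 at 2000 nM.

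Levels before the response were set against its size over 55 lines, to see whether genes that handle gemcitabine track it. None of 33 relations passed at 200 nM. The smallest Pearson p was that of the level of TYMS, the thymidylate synthase, against the SD over genes of the line's changes (r = 0.357, permutation p = 0.00755, adjusted p = 0.245, rho = 0.291, permutation p = 0.0319, adjusted p = 0.351). Without the lines COLO-205 and OVCAR-4 r was 0.303, and with tissue means removed 0.334. RRM1 against the same measure gave r = 0.308 (permutation p = 0.0224, adjusted p = 0.245), and its rho of 0.374 had the smaller permutation p of 0.00473 (adjusted p = 0.156). With the 2000 nM response of 56 lines 2 of 33 relations passed, each against the same SD over genes. RRM1 gave r = 0.456 (permutation p = 0.00033, adjusted p = 0.0109, rho = 0.498, permutation p = 0.00015, adjusted p = 0.00495), with r = 0.455 without COLO-205 and OVCAR-4 and 0.428 with tissue means removed. TYMS gave r = 0.398 (permutation p = 0.00248, adjusted p = 0.0409), with r = 0.344 and 0.338, while its rho of 0.35 (permutation p = 0.00863) did not pass (adjusted p = 0.142). The SD over genes also went with the change in the actin probe difference, with r = 0.398 (adjusted p = 0.00208, rho = 0.503, adjusted p = 0.00014) at 200 nM and r = 0.522 (adjusted p = 8e-05, rho = 0.566, adjusted p = 2e-05) at 2000 nM by permutation, 2 relations in all. Without the 2 lines farthest from the median these r were 0.395 and 0.532, and with tissue means removed 0.306 and 0.572.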

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

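The tests on the MCF7 and A498 arrays and the counts without those arrays were chosen after the result was seen. So were the counts with the actin covariate, the GAPDH values and the relation of actin to the SD over genes.

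Among groups of 4 to 10 lines of 1 tissue, 7 of 64 sets of list means held a line far from the others. By chance 3.2 would be expected if the sets were independent. They are not, since both doses use the same lines and 0 nM arrays. HCT-116, IGR-OV1 and SNB-75 are each counted at both doses, so the count of 7 does not show an excess. HCT-116 had p53 target means of 1.66 and 1.84 at 200 and 2000 nM at 24 h, against 0.224 to 0.438 and 0.314 to 0.471 in the other colon lines. IGR-OV1 had 1.21 and 1.16, against 0.104 to 0.444 and 0.106 to 0.47 in the other ovarian lines. For interferon-stimulated genes SNB-75 had 1.44 and 0.86, against 0.203 to 0.386 and 0.103 to 0.311 in the other CNS lines. MCF7 had a p53 target mean of -1.88 at 2000 nM, against 0.157 to 0.463 in the other breast lines.

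The MCF7 value rests on the array labelled 0 nM at 24 h, whose p53 target mean was 9.003, and that labelled 2000 nM, at 7.13. By profile, the first was nearer to the treated profile by 0.0623 where the other 55 lines had -0.446 to -0.0954, and the second was nearer to the 0 nM profile by 0.251 where 109 other treated arrays had -0.588 to 0.0246. The tables argue against a response of MCF7 to the drug unlike that of other lines as the whole account, since such a response leaves the array labelled 0 nM in place, and its margin was 0.0623. An interchange of the labels of these 2 arrays is a candidate explanation for which each array is out of place in the direction needed (smaller margin 0.0623), and the A498 array labelled 2000 nM at 6 h was nearer to the 0 nM, 24 h profile by 0.41 (107 others -0.74 to -0.0789), so a wrong label or RNA of another sample stays open there. Without these 3 arrays 5408 genes changed at 24 h at 200 nM, 5548 at 24 h and 1906 at 6 h at 2000 nM, and no label was altered.

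The changes at 24 h came with a higher actin 3′ minus 5′ probe difference, a sign of RNA quality (mean change 0.21 and 0.252), while that of GAPDH moved by 0.0396 and 0.028, with an SD over lines of 0.26 and 0.198. With that difference as a covariate 4942 genes changed at 200 nM and 4838 at 2000 nM, and 4583 and 4372 of them were called in the same direction without it. Lines with a larger actin change had a larger SD over genes of their changes at 24 h (r = 0.398 and 0.522). The covariate was related to 1925 and 1617 genes at 24 h. At 2 h, where 14 and 18 genes changed, it was related to 3616 and 3909 genes. The SD over genes already averaged 0.21 and 0.218 at 2 h, with r to the actin change of 0.0296 and 0.219. It thus does not read the drug response alone. The calls that stayed argue against RNA quality, as far as actin reads it, as the whole cause of the changes, while a part in their size, and what actin does not read, stay open. Drug exposure may itself alter RNA quality, since actin was higher in treated than in 0 nM arrays at 24 h, and the 4942 and 4838 genes do not settle that.

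The 429 genes that differed between 2000 and 200 nM at 24 h changed little, and the doses were on different arrays. If the arrays had differed before the drug acted, the genes would differ in the same direction at 2 h, and 49.4% did, within the 36.4 to 62.2% of sign-flipped data. That argues against a difference present from the start. At 6 h, on other arrays, 77.9% of these genes differed in the same direction as at 24 h. No sign-flipped range was made for 6 h, so a difference between arrays at 24 h alone was not tested. A stronger form of the 200 nM response is a candidate explanation: 66% of genes called in one part of the lines moved the same way from 0 to 200 nM in the other part, with an SD of 14.8 over splits, and 15 of 50 splits called no gene. Without MCF7 77.6% of called genes did, and with the 500 smallest p in place of called genes 64.3% (SD 5.77), or 69.6% without MCF7.

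The response differed between times for 702 genes (2 and 6 h) and 4193 genes (6 and 24 h) at 200 nM, and for 906 and 3984 at 2000 nM. It differed between tissues for 1814 genes at 200 nM and 1990 at 2000 nM. Probe sets with no gene name, which the gene tests leave out, changed at 24 h in 638 of 2108 cases at 200 nM (199 up, 439 down) and 640 at 2000 nM (439 down).

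Counts were compared with those after random reassignment, with 100 assignments each, the real one included. Flipping the sign of each line's difference gave as many genes in 1 of 100 cases, the real one, for each dose against 0 nM. That argues against chance, at the smallest share that 100 assignments can give. Sign flips cannot tell the drug from any other steady difference between the arrays of 2 doses. The highest other counts were 2, 7 and 2 at 2, 6 and 24 h at 200 nM (real 14, 1181 and 5422) and 1, 2 and 1 at 2000 nM (real 18, 1805 and 5399). The share was likewise 1 of 100 for the doses compared at 6 and 24 h (highest other 2 and 2, real 679 and 429). At 2 h the real count was 0 and the highest other 1, and since any assignment reaches 0, the 100 of 100 that did say nothing about chance. For the change in response between times, 1 of 100 gave as many, with highest others of 27 and 1 at 200 nM and 1 and 1 at 2000 nM. For untreated cultures the highest others were 16 and 1 (real 2666 and 4277), and for lines assigned at random to tissues 10 and 1 (real 1814 and 1990), with 1 of 100 each.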

How the results depend on the processing

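Leaving out the arrays labelled MCF7 0 nM and 2000 nM at 24 h and A498 2000 nM at 6 h, the actin covariate, and list tests outside the comparisons with 0 nM were chosen after seeing the data. Without pairing by line the counts at 2, 6 and 24 h were 0, 56 and 1105 (200 nM) and 1, 83 and 1358 (2000 nM), 0 at 6 h and 0 at 24 h between doses, 2 and 78 (200 nM) and 13 and 53 (2000 nM) for changes in the response between times, and 11 and 165 in untreated cultures. All genes called without pairing were also called with it, in the same direction. In that setting the spread between lines stays in the error, which is its construction. In 1 fit over all arrays the counts were 3 and 454 at 2 and 6 h at 200 nM, 3 and 957 at 2000 nM, 1 and 23 between doses at 6 and 24 h, 127 and 258 for the response from 2 to 6 h at the respective doses, and 1548 in untreated cultures from 2 to 6 h, and the cause was not tested. Without leukemia lines 9 genes changed at 2 h at 200 nM, with fewer lines. Centred arrays gave 2851 genes at 6 h at 2000 nM, and the cause was not tested. Every probe set on its own gave 8307 and 8231 at 24 h, over more items.

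The lists called were 3, 12 and 12 at 200 nM and 9, 11 and 12 at 2000 nM at 2, 6 and 24 h. With an estimated correlation 0 were called at 24 h at 200 nM, 4 at 2 h, 6 at 6 h and 0 at 24 h at 2000 nM. At 2 h at 2000 nM fry called 5 and the test without pairing 2. Over all comparisons with 0 nM fry gained 17 list calls and lost 4. Among the gains by fry at 200 nM was the gemcitabine list at 6 h (adjusted p = 0.00319) and 24 h (0.000181). Without the 3 arrays and with an estimated correlation 1 was called at 200 nM at 24 h (apoptosis regulators), and 7 (with replication stress and DNA repair) and 0 at 2000 nM at 6 and 24 h. The correlation estimated between members widens these tests by construction. Correlation of the doses over genes called at either dose was 0.946, 0.939 and 0.986 at 2, 6 and 24 h, but choosing called genes against shared 0 nM arrays by itself gives a high value, so it shows no likeness of its own. Relations of baseline level to response numbered 2 with the 2000 nM response and 2 with that response without the 3 arrays, against 0 at 200 nM, and the cause was not tested. In untreated cultures from 2 to 6 h, the mean of probe sets gave RRM2 0.0296 (adjusted p = 0.317) and TYMS -0.0209 (adjusted p = 0.72), against -0.08 and 0.06, and no list reversed; the cause was not tested. Over all named genes and settings 6400 values kept direction and call, 622 lost the call, 11 gained it and 2 reversed, with 333 of the losses without pairing and 137 in 1 fit over all arrays. The brightness of a gene limits what arrays can show. Leaving out the dimmest 25% of genes moved no count by over 1.5 times, but ended the calls of histones at 2 h (adjusted p = 0.20, 8 of 26 members left), hypoxia at 6 h (0.0651) and ATF4 at 24 h (0.0609), each at 200 nM. Without the 3 arrays the gemcitabine list was called at 6 h at 2000 nM (adjusted p = 0.044).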

Other observations

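The p53 relations over lines were set out as tests before their values were seen. The rule for a relation near 0, which asks whether its 95% interval excludes 0, was chosen after the result was seen, as were the examples of genes below.

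Tissues differed in further ways at 24 h at 200 nM. Leukemia lines had higher H2AC17, a core histone, by 1.4 (SD 1.13, 6 of 6 lines) and TM6SF1 by 1.07, and the desaturase SCD5 was at 0.842 in leukemia lines against -0.547 in breast lines. Colon lines had ABAT, a GABA transaminase, at 1.81 (SD 0.608), and RHOC, a small GTPase, was at 0.839 in colon, 0.667 in leukemia and -0.554 in CNS lines. HSPBAP1 was at 1.34 in renal lines. At 2000 nM the folate receptor FOLR1 was at 1.47 (SD 1.07) in leukemia lines, KLK10, a secreted protease, at 1.12 in colon lines, and the lipid droplet protein PLIN3 at 0.651 in colon against -1.29 in CNS lines.

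Single lines stood at the ends of several lists at 200 nM and 24 h. G1/S and DNA replication genes were lowest in the lung lines A549 (-0.548) and NCI-H460 (-0.383) and highest in SNB-75 (1.72). Histones were highest in the leukemia lines SR (0.701) and HL-60 (0.53), AP-1 genes in the renal line 786-0 (2.2), and interferon-stimulated genes in SNB-75 (1.44) and the breast line BT-549 (1.14).

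A hypothesis on the spread of the p53 target change was that lines with more p53 target RNA before treatment show a larger rise. Over 55 lines the level on the 0 nM, 6 h array and the change at 24 h at 200 nM had r = 0.512 (permutation p = 0.00013, rho = 0.513, p = 5e-05), with r = 0.514 without HOP-92 and UO-31 and 0.47 with tissue means removed. The level and the change share no array, and the data are consistent with the hypothesis, which may reflect which lines have active p53, a property not tested here.

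Another hypothesis was that lines with a larger rise of p53 targets have a lower change of cell cycle transcripts, as 4 relations adjusted together. The G1/S mean was above 0 in 50 of 55 lines at 24 h at 200 nM (mean 0.395). A lower change of G1/S genes is thus mostly a smaller rise, not a loss. The rise of p53 targets at 6 h against the change of G1/S genes at 24 h had r = -0.567 over 53 lines (adjusted p = 8e-05, rho = -0.426, adjusted p = 0.00568), with r = -0.412 (p = 0.00324) without A549 and NCI-H460 and -0.561 with tissue means removed. With both changes at 24 h r was -0.474 over 55 lines (adjusted p = 0.00084) and -0.299 (p = 0.0313) without A549 and NCI-H460, while rho of -0.225 did not pass (adjusted p = 0.198), and both sides share the 0 nM arrays. For G2/M genes r was 0.0967 (adjusted p = 0.656, 95% interval -0.178 to 0.358) against the 6 h rise and 0.00656 (adjusted p = 0.963, interval -0.259 to 0.271) against the 24 h rise. Both lie above 0, where the hypothesis needs a value below, by less than their spread, so the relation to G2/M genes cannot be told apart from none with these lines. Without A549 and NCI-H460 the first became 0.303 (p = 0.0298, not adjusted), against the direction of the hypothesis.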
